A study of Zea mays with 6 samples.

How the data were processed

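RNA was sequenced from the third leaf of maize (Zea mays) seedlings of 2 inbred lines, B73 and W9706, on day 7 of drought, per the labels. Per the labels' protocols, seedlings grew in soil in beakers to the 3-leaf stage at 26°C with 14 h of light and 10 h of dark and a relative humidity of 50 ± 5%. Total RNA was extracted with TRIzol and an RNA purification kit and treated with DNase I, and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. That kit does not mark the strand of the RNA. Each line had 3 libraries. The labels do not say whether replicates came from separate plants, beakers or days, so p-values measure the spread between these libraries, which may be technical. No watered libraries were analysed here, so no response to drought could be computed, and the sole contrast was W9706 against B73 under drought.

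The deposited files hold whole-number counts per gene and library, in the layout of the STAR aligner's gene count table, and STAR is named in the submitters' processing notes. The version, the genome build and the annotation are not given in the sources used here. Each file opens with 4 summary lines (unmapped, multimapping, no feature and ambiguous), then lists 46430 genes with a count made without regard to strand and a count for each strand. Multimapping reads were listed as 0 in all 6 libraries, and the alignment settings are not given in the sources used here. Such reads may therefore be among the unmapped reads. Gene counts of this layout take uniquely aligned reads, so that paralogs, the inverted repeat of the plastid genome and organelle genes with copies in the nuclear genome are uncertain and may be undercounted. Overlapping genes and antisense partners cannot be told apart in these counts. The summary lines were kept out of library sizes and tests. Of all reads listed, unmapped reads made up 12.7% to 13.8%, reads in no annotated gene 3.68% to 4.33% and ambiguous reads 1.06% to 1.16%. The unstranded column was used. The first strand column held 50.1% to 50.3% of the stranded counts. Counts assigned to genes ranged from 21084151 to 32088105 per library. Where reads of a gene could be counted at all, a gene with 0 counts could still have a level of up to 0.0935 to 0.142 CPM (edgeR's count scaled by the library total), which is 3 counts of the library's total and covers counting error only.

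Genes were tested with edgeR 4.0.16 in R 4.3.3: filtering by group with filterByExpr (22135 genes kept), TMM normalization, robust dispersion estimates and the quasi-likelihood F test, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are W9706 relative to B73. The standard error of a log2 fold change was derived from the F statistic as the fold change divided by its square root. CPM values use the TMM-scaled library sizes, and shares of counts use the library totals without TMM factors. Sets of genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, and again with the correlation estimated. Measures of whole libraries were compared by exact two-sided permutation tests, for which 3 against 3 libraries cannot give a p below 0.1.

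The edgeR test was tested on simulated data drawn for the 22135 genes with the means, dispersions and library sizes of W9706 against B73, with 200 genes changed, drawn from those with a mean of at least 20 counts. It recovered 70 of 100 genes changed 2-fold and 91 of 100 changed 4-fold in the right direction, and called 14 unchanged genes among 175 calls.

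The nuclear gene models carry identifiers with the prefix Zm00001d, used for gene models of the B73 reference genome. None of these 44146 identifiers could be paired with a name from the files or from the RefSeq gene table used here (assembly Zm-B73-REFERENCE-NAM-5.0, used for names alone). The table matched 518 identifiers, of which 481 had a name, all of them organelle genes or microRNA precursors. The 37 gene lists fixed before the data were examined (drought, hormone, photosynthesis, defence and tissue markers) therefore had 0 matched members and were not tested, and no markers of other tissues could be checked. Families of organelle genes were defined from gene symbols once the identifiers were known and before their values were seen. The sets by genome (all tested mitochondrial and all tested plastid genes) were chosen after the values were seen. The rule for genes to be named asked for named genes past the threshold with the largest changes and a mean CPM of at least 1 in both lines, or under 1 in one line and at least 10 in the other, for the called members of the 37 fixed lists with the smallest p, and for a few fixed drought and photosynthesis genes. It gave 0 named genes, since the sole named gene past the threshold, petD, had a mean of 0.336 CPM in W9706 and 1.04 CPM in B73 and is in none of the fixed lists. In its place the 20 named genes tested are plotted and some of them described, and of the nuclear identifiers the 2 largest rises and the 2 largest falls among genes past the threshold, without overlap between the groups and with a mean CPM of at least 1 in both.

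Whether equal replicate numbers pair the libraries is not stated. Deviations from the group means correlated at 0.22, 0.11 and 0.13 for replicates 1, 2 and 3 across genes. Libraries of different number gave up to 0.107, for B73 replicate 2 with W9706 replicate 3, about as high as for its partner of equal number. Each same-number value exceeded 0.1, the limit set for pairing, but so did that of B73 replicate 2 with W9706 replicate 3. The limit therefore does not establish that equal numbers are pairs. The fit with the replicate number as a block is given as an alternative to the unblocked design fixed beforehand. Alternatives fixed before the data were examined were RLE and upper quartile normalization, DESeq2 1.42.0, other filters on low counts, the strand columns, leaving out each replicate, the replicate block, scaling without the 100 most abundant genes, leaving out organelle genes and glmTreat. Scaling by library size alone, sets by genome, leaving out 2 libraries together and other filters and normalizations for the correlations between libraries were added after seeing the data.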

Results

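Gene expression was profiled by RNA sequencing in leaves of the maize inbred lines B73, the line of the maize reference genome, and W9706, on day 7 of drought. Each line was represented by 3 libraries. Counts assigned to genes were 26631103, 24154525 and 21084151 in B73 replicates 1 to 3 and 25054048, 25747666 and 32088105 in W9706 replicates 1 to 3. Between 25833 and 27183 genes had at least 1 count in a library. The comparison addressed how the leaf transcriptomes of the lines differed under drought.

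Libraries separated by line. Correlations of log2 CPM were 0.970 to 0.985 between replicates of a line and 0.897 to 0.943 between lines. The first principal component held 70.3% of the variance and placed the B73 libraries at -72.8 to -51.1 and the W9706 libraries at 51.3 to 77.5. No pair of libraries was a duplicate, since counts differed by at least 11.2 times the sampling variance (chi-square per degree of freedom) in every pair. Within each line 1 library lay nearer the other line, namely B73 replicate 2 and W9706 replicate 1.

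**Figure D1:**
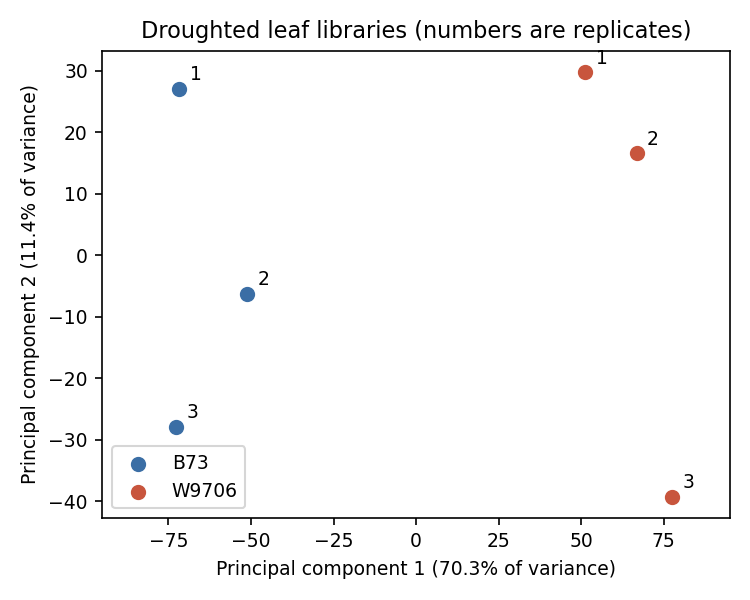
Position of the 6 libraries on the first and second principal components of log2 CPM, with points for libraries, colours for lines and numbers for replicates. The lines separate along the first component (70.3% of variance), with B73 at -72.8 to -51.1 and W9706 at 51.3 to 77.5.

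Of 22135 genes tested, 3367 were higher and 4197 lower in W9706 than in B73 at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), together 34.2% of the genes. The median change among these 7564 genes was 0.84 on the log2 scale in size. Changes of more than 2-fold were found for 3074 genes, 1236 higher and 1838 lower in W9706. Changes of more than 8-fold were found for 122 genes higher and 214 lower, and of more than 32-fold for 26 higher and 26 lower. Lower counts in W9706 need not mean lower expression, since reads of W9706 that fail to align would also lower them. Groups did not overlap in 7526 of the 7564 genes, which selection by a test on the same libraries nearly ensures. Over all tested genes they did not overlap in 50.6%, where chance gives 10% on average over groupings of the libraries. Genes vary together across libraries, so a single grouping can lie far from 10%, and this share is no test. Without W9706 replicate 2, 2070 genes were higher. The balance of directions depended on the scaling. Upper quartile normalization gave 4300 higher and 3680 lower genes, and library size alone 8165 higher and 2622 lower, with the median of all genes moved from 0.01 to 0.29 on the log2 scale. A test against a 2-fold change itself (edgeR glmTreat) called 844 genes, 276 higher and 568 lower in W9706.

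**Figure D2:**
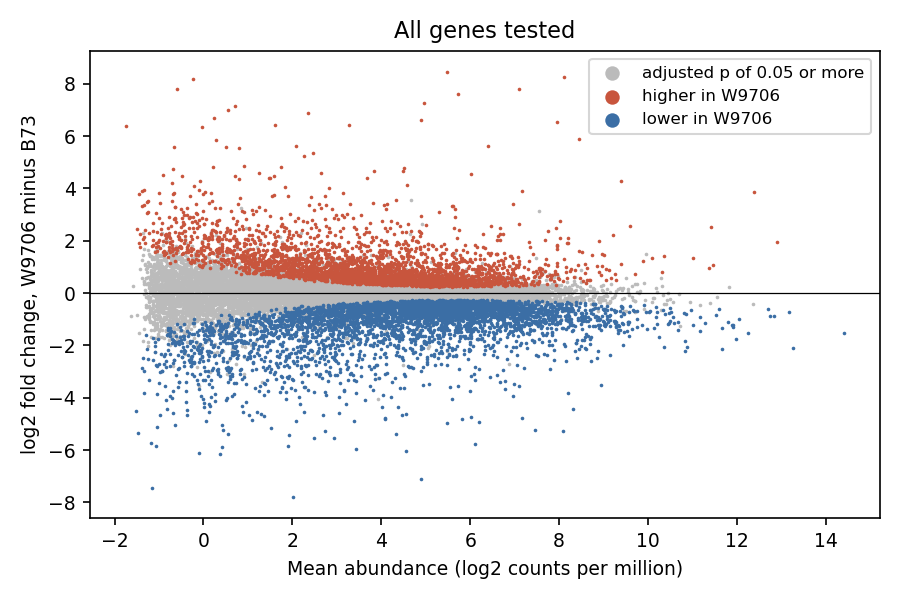
Log2 fold change (W9706 minus B73) of each of the 22135 genes tested against its mean abundance in log2 CPM. Coloured points are genes with an adjusted p under 0.05, 3367 higher and 4197 lower in W9706.

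Among nuclear genes with a mean of at least 1 CPM in both lines, the 2 largest rises and the 2 largest falls were taken. Zm00001d023984 had 549 ± 31.0 CPM in W9706 and 1.75 ± 1.41 CPM in B73 (SD, n = 3 each), a log2 fold change of 8.26 ± 0.56 (SE) with an edgeR adjusted p of 0.000249. Zm00001d038870 had 272 ± 163 CPM in W9706 and 1.28 ± 1.17 CPM in B73, a log2 fold change of 7.80 ± 0.84 with an edgeR adjusted p of 0.00131. Without B73 replicate 3 the order of these rises turned, with log2 fold changes of 7.84 and 8.80, and without B73 replicate 2 that of Zm00001d023984 was 9.04. Zm00001d028561 fell from 135 ± 40.5 CPM in B73 to 2.39 ± 1.71 CPM in W9706, a log2 fold change of -5.78 ± 0.52 with an edgeR adjusted p of 0.000578. Zm00001d024903 fell from 533 ± 177 CPM in B73 to 13.6 ± 9.05 CPM in W9706, a log2 fold change of -5.28 ± 0.55 with an edgeR adjusted p of 0.000938. Without W9706 replicate 3 these log2 fold changes were -6.57 for Zm00001d028561 and -5.98 for Zm00001d024903. Genes below 1 CPM in one line, some with larger changes, were left out by this limit. Neither the files nor the gene table used here pair these identifiers with gene names. The identifiers are those of B73 gene models, so falls in W9706 could also come from reads that fail to align, which was not measured.

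Abundant genes fell more often than they rose in W9706. Of the 100 genes with the highest mean abundance over all libraries, 55 were lower, 11 were higher and 34 did not pass the edgeR test, and their median log2 fold change was -0.66. Of the 12135 genes ranked beyond the first 10000, 1841 were higher and 1614 lower, with a median of 0.07. The excess of falls among the 100 most abundant genes held under upper quartile scaling, with 52 lower and 12 higher, and under library size alone, with 40 lower and 16 higher. Without B73 replicate 2 and W9706 replicate 1 there were 44 lower and 12 higher, and without W9706 replicate 2 there were 42 lower and 7 higher. The most abundant genes of each library also took a larger share of its counts in B73. The top 100 genes held 26.3 ± 1.05% of counts in B73 and 21.3 ± 0.42% in W9706 (SD, n = 3), and the top 10 held 10.1 ± 1.02% and 7.66 ± 0.09%. The lines did not overlap in either share, and the exact permutation p of 0.1 is the smallest that 3 against 3 libraries allow (0.15 after adjustment over 9 library measures).

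**Figure D3:**
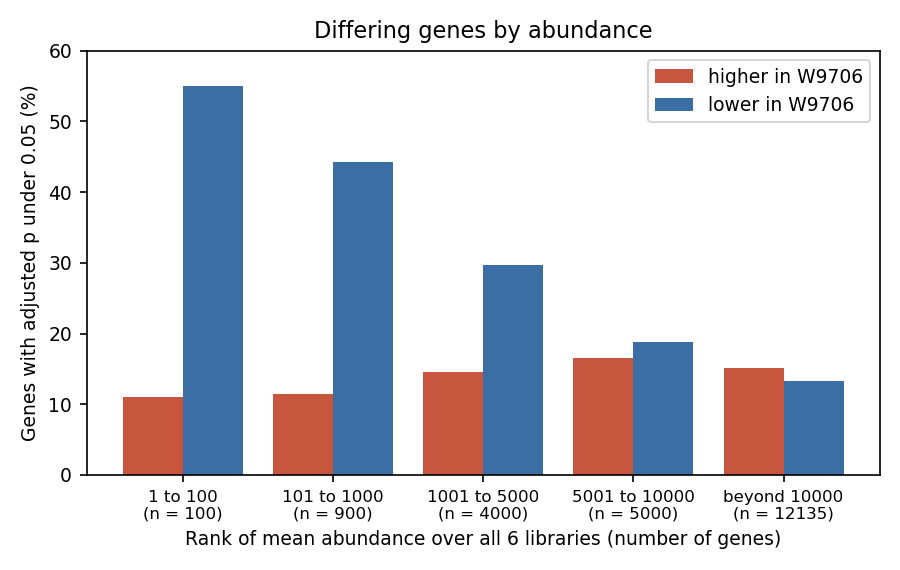
Percentage of genes called higher or lower in W9706 (adjusted p under 0.05) in classes of genes ranked by mean abundance over all 6 libraries. Among the 100 most abundant genes 55 were lower and 11 higher, and beyond rank 10000 there were 1614 lower and 1841 higher of 12135.

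Plastid-encoded genes contributed few counts, 305 to 407 per library, or 14.8 ± 0.43 CPM of the library totals in B73 and 12.9 ± 1.54 CPM in W9706 (SD, n = 3, exact permutation p of 0.1, the smallest possible, and 0.15 after adjustment). Of the 157 plastid genes listed, 25 had any count. The genes of the photosystems were almost unmeasured: the 5 photosystem I genes had 3 counts and the 15 photosystem II genes 5 counts over all 6 libraries. rbcL, which encodes the large subunit of Rubisco, and psbA, which encodes the D1 protein of photosystem II, had 3 counts each over all libraries. The 4 genes of the plastid RNA polymerase had 0 counts. The 12 genes of the NDH complex had 69 counts and the 39 transfer RNA genes 19. None of these families had a member with enough counts to be tested. The 25 ribosomal protein genes had 80 counts, the 6 cytochrome b6f genes 98 and the 6 ATP synthase genes 76, with 1 tested member each. ycf3 alone gave 1552 of the 2124 plastid counts.

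All 5 tested plastid genes had negative log2 fold changes with TMM, RLE and upper quartile scaling, and 4 of 5 with library size alone, where ycf3 was at 0.01. With TMM 1 of them, petD, passed the edgeR test, as it did with DESeq2 (adjusted p of 0.0313), and it was singled out after its values were seen. petD, which encodes subunit IV of the cytochrome b6f complex, fell from 1.04 ± 0.37 CPM in B73 to 0.34 ± 0.20 CPM in W9706 (SD, n = 3 each). With TMM scaling the 3 W9706 libraries all lay below the 3 B73 libraries, but by library totals W9706 replicate 2 (16 of 25747666 counts) lay above B73 replicate 2 (14 of 24154525 counts). Its log2 fold change was -1.63 ± 0.51 (SE), with an edgeR adjusted p of 0.0397 over all genes and 0.0626 adjusted over the list alone. The call rests on 6 to 32 counts per library and was lost with the replicate block (edgeR adjusted p of 0.0655). It was also lost without B73 replicate 1 (0.125), B73 replicate 3 (0.104), W9706 replicate 1 (0.111) or W9706 replicate 3 (0.106). Values for the other 4, none past the threshold, were -1.20 ± 0.53 for atpF (a subunit of the plastid ATP synthase), -0.83 ± 0.55 for rps16 (a ribosomal protein), -0.79 ± 0.32 for matK (an intron maturase) and -0.27 ± 0.15 for ycf3 (a photosystem I assembly factor) on the log2 scale. As a set the 5 had a median log2 fold change of -0.83, and of -0.55 with library size alone (camera with TMM, adjusted p = 0.0464 with the preset correlation, adjusted p = 0.316 with an estimated correlation). This set was chosen after its values were seen, and its call was lost without B73 replicate 1 (camera adjusted p = 0.0738), B73 replicate 3 (0.0596), W9706 replicate 1 (0.0729) or W9706 replicate 3 (0.0723).

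Mitochondrion-encoded genes gave 3623 to 8197 counts per library, and their share did not separate the lines, at 203 ± 35.1 CPM of the library totals in B73 and 203 ± 51.5 CPM in W9706 (SD, n = 3, exact permutation p of 1). Most of these counts came from 2 ribosomal RNAs. rrn26 had 168 ± 31.5 CPM in B73 and 142 ± 33.2 CPM in W9706, and rrn18 had 35.4 ± 5.40 and 28.6 ± 9.55 CPM. The 9 ribosomal protein genes had 506 counts over all libraries (4 tested), the 4 genes of complexes III and IV 427 (2 tested) and the 6 of complex I 214 (1 tested). The 4 cytochrome c maturation genes had 166 counts and the 6 ATP synthase genes 119, with 1 tested member each, and the 138 open reading frames 895 (3 tested). Some core genes, among them cob of complex III, nad7 of complex I and atp6 of the ATP synthase, were at 0 counts in all 6 libraries. None of the 15 tested mitochondrial genes passed the edgeR test over all genes or adjusted over the list alone, while 4 had an unadjusted p under 0.05. DESeq2 called 0 of 48. The log2 fold changes were negative for 13 of 15 genes, and for 12 of 15 with library size alone, where rrn26 was at 0.04. cox1, which encodes subunit 1 of cytochrome c oxidase, had 2.46 ± 0.21 CPM in B73 and 1.37 ± 0.60 CPM in W9706 (edgeR adjusted p of 0.0992), and nad4, a subunit of complex I, had 1.32 ± 0.59 and 0.63 ± 0.29 CPM (edgeR adjusted p of 0.131). The median log2 fold change of the set was -0.67, and -0.39 with library size alone (camera with TMM, adjusted p = 0.0263 with the preset correlation, adjusted p = 0.423 with an estimated correlation). This set was chosen after its values were seen. Without W9706 replicate 1 its median was -0.28 (camera adjusted p = 0.0729), and without B73 replicate 1 it was -0.53 (camera adjusted p = 0.0738).

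**Figure D4:**
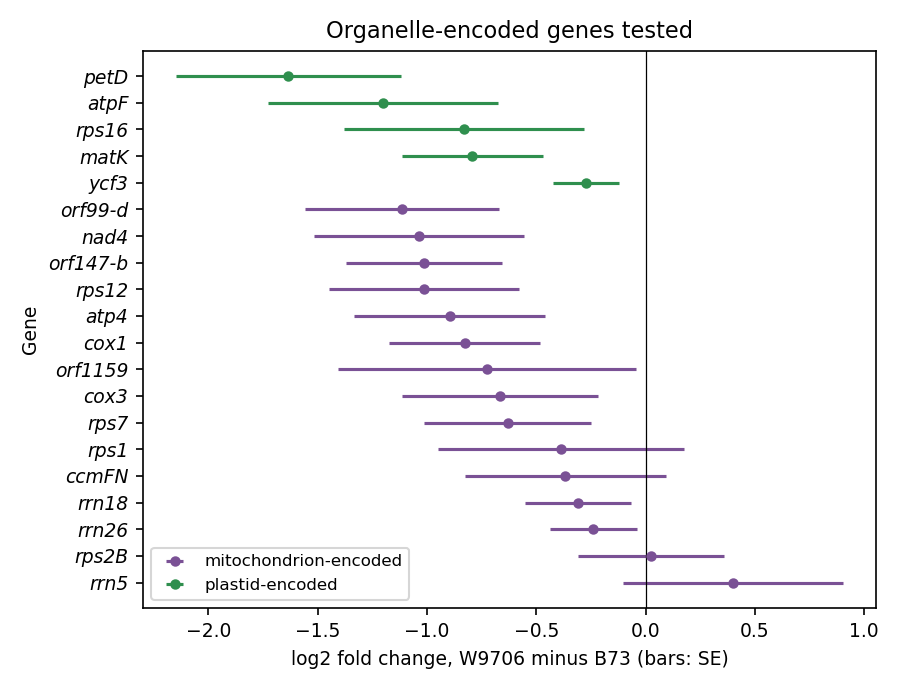
Log2 fold change (W9706 minus B73) of the 20 named organelle-encoded genes tested, with bars for the standard error and colours for the genome. With TMM scaling all 5 plastid genes and 13 of 15 mitochondrial genes lie below 0, with library size alone 4 and 12 (ycf3 and rrn26 turn), and petD alone passed the test.

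MicroRNA precursor genes, 154 in the files, had 0 counts in every library. Multimapping reads were listed as 0 and the alignment settings are not given in the sources used here, so these zeros set no limit on their level. Of 101 other annotated non-coding RNA genes tested, 3 were higher and 2 lower in W9706 in the edgeR test over all genes and 0 passed when adjusted over the list alone, with 9 at an unadjusted p under 0.05. With the replicate block 1 was higher and 2 lower, and DESeq2 called 3 of 235.

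Few genes were counted in one line alone. With a mean of at least 20 counts in one line and 0 counts in all 3 libraries of the other, 1 gene was found in B73 alone, at a mean of 37 counts, and 4 in W9706 alone, at means of 20 to 42.7 counts. These limits were set on counts not corrected for depth. W9706 libraries were deeper on average (27629940 assigned counts against 23956593), which favours genes found in W9706 alone. The counts of the B73 gene came mostly from replicate 1, and 0 genes met the criterion in B73 without that library. Leaving out B73 replicates 2 or 3 or W9706 replicates 1 or 3 gave, in this order, 4, 2, 7 and 9 genes in B73 alone. Leaving out B73 replicates 1 or 2 or W9706 replicate 2 gave, in this order, 11, 9 and 2 genes in W9706 alone. By comparison 19628 genes reached a mean of 20 counts in both lines. Allowing up to 2 counts per library in place of 0 gave 8 genes in B73 alone and 18 in W9706 alone. A mean of at least 50 counts left 0 and 0. The share of unmapped reads was 13.1 ± 0.62% in B73 and 13.2 ± 0.24% in W9706 (SD, n = 3, exact permutation p of 0.9), and the lines overlapped. Reads outside annotated genes made up 3.73 ± 0.05% of reads in B73 and 4.24 ± 0.08% in W9706 (SD, n = 3, exact permutation p of 0.1, the smallest possible).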

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

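Scaling by library size alone, leaving out 2 libraries together, the sets by genome and all alternatives for the correlation between lines were chosen after seeing the data. The number of genes differing between the lines stayed within 1.5 times of 7564 under all alternatives run, planned and added. Among these were DESeq2 (7962), no filter on low counts (7403) and the replicate block, which called 8047 genes, 7211 of them shared with the unblocked fit. The genes called changed more than their number. Library size alone called 10787 genes but kept 5989 of the 7564 calls, and 25 of the 7564 changed sign. Upper quartile normalization kept 7047 of the 7564 and DESeq2 7289. Of the 20 organelle genes tested and the 4 genes named by identifier, the replicate block changed the call of petD alone. It gave 11 higher and 58 lower among the 100 most abundant genes, and 1 higher and 2 lower non-coding RNA genes. No gene called here was called in the opposite direction by DESeq2, another normalization, the block or a fit without a replicate; the first strand column and the sum of the strand columns each reversed 1 call. Leaving out a replicate gave 5133 (without W9706 replicate 2) to 6751 genes, 2070 (without W9706 replicate 2) to 2977 higher and 3063 to 3969 lower, 2617 to 3147 over 2-fold, 1012 to 1299 higher and 1605 to 1848 lower over 2-fold. Without B73 replicate 2 and W9706 replicate 1 together 5305 genes differed and 2240 were higher. Scaling by library size alone gave 8165 higher and 2622 lower genes, of which 2256 and 1223 by over 2-fold, so the balance of directions rests on the normalization. glmTreat called 844 genes (276 higher, 568 lower), by construction a stricter test. Genes counted in one line alone numbered 0 and 0 with a mean of at least 50 counts, and 8 in B73 and 18 in W9706 with up to 2 counts allowed; leaving out a replicate gave 0 to 9 in B73 and 2 to 11 in W9706. The mean correlation between lines was 0.921, 0.962 with no filter and 0.906 with a CPM of at least 1 in 3 libraries. The set medians, -0.67 for mitochondrial and -0.83 for plastid genes, lost their call with an estimated correlation. fry, which tests a set against no change and not against other genes, gave an adjusted p of 0.133 for the mitochondrial and 0.0295 for the plastid set. Under library size alone the medians were -0.39 and -0.55. Leaving out a replicate gave -0.86 to -0.28 and -1.15 to -0.77, with calls lost without B73 replicate 1 or W9706 replicate 1 (both sets) and without B73 replicate 3 or W9706 replicate 3 (plastid). petD also lost its call in strand column 3 (-1.45), under library size alone (-1.35) and without the 2 libraries together (-1.66). The 2 rises and 2 falls named by identifier kept direction and call in the 20 alternatives run for each, glmTreat not among them. In simulation 70% of 2-fold changes were recovered at this depth among genes with a mean of at least 20 counts, and recovery at lower counts, as of petD, was not simulated. The simulation changed 200 of 22135 genes, while 34.2% were called in the data, so its recovery need not hold for this contrast.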

Other observations

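The tests of unmapped reads and strong changes, of mixed RNA and of exchanged libraries, and the interval of the ratio of undetected genes, were chosen after the results they measure had been seen in whole or in part.

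The real grouping gave 7564 genes and the other 9 of the 10 splits of the 6 libraries into 3 and 3 gave 0 at most, so 1 split reached the real count. With 10 splits the share cannot fall under 0.05. Every other split puts libraries of both lines in each group, so the difference between the lines counts as spread and favours 0. The comparison therefore adds no support to the calls. Of the 4 splits that part every replicate number, the 3 others also gave 0.

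Maize inbred lines are known to differ in gene content and sequence, so genes missing from W9706, or reads of W9706 that fail to align, were expected to leave more genes undetected in W9706 than in B73. With 1 gene undetected in W9706 against 4 in B73 the ratio was 0.25 (95% exact binomial interval 0.00508 to 2.53), on counts not corrected for depth. The order turned without W9706 replicate 1 (7 against 4) or W9706 replicate 3 (9 against 3). Leaving out a W9706 library asks for 0 counts in fewer libraries, which can only add genes undetected in W9706. These turns therefore say nothing of the direction. The interval includes a ratio of 1, so these few genes leave the direction open. Of 20073 genes with a mean of at least 20 counts in B73, 1 was at 0 in all W9706 libraries, and 8 with up to 2 counts allowed. Complete loss of counts was therefore rare among such genes. It could not be the source of most falls in any case, since only 214 of 4197 lower genes were over 8-fold lower. Losses that leave more than 2 counts in a library are not covered. Partial failure to align was not measured. A W9706 genome close to the one the reads were aligned to is a hypothesis that the values also leave open. The share of unmapped reads differed by 0.066 percentage points, less than the spread within B73. Multimapping reads were listed as 0 and may be among the unmapped, so this share does not isolate reads that fail to align. With TMM scaling, 26 genes were over 32-fold lower and 26 over 32-fold higher in W9706, but over 8-fold 214 were lower and 122 higher. The 8-fold and 32-fold counts were not computed under other scalings. Over 2-fold the balance turned with library size alone, at 2256 higher and 1223 lower. The share of reads outside annotated genes did not overlap between the lines (3.73 ± 0.05% in B73, 4.24 ± 0.08% in W9706). Counts carry no sequence, and neither the relation of W9706 to B73 nor the line labels were tested.

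Libraries of each line spread along the axis that separates the lines. Across genes, which are not independent replicates, deviations from the group mean correlated with the fold change at -0.12, 0.30 and -0.16 for B73 replicates 1 to 3 and at -0.28, 0.05 and 0.21 for W9706 replicates 1 to 3, and since deviations sum to 0 within a line, some library leans towards the other line in any case. Tests of depth and of an exchange of B73 replicate 2 and W9706 replicate 1 argued against both, since after thinning every library to 21084151 counts the correlations of these libraries were 0.30 and -0.29 (the smaller in size 0.285), and the lowest correlation within a line exceeded the highest between lines by 0.0269. W9706 RNA mixed into B73 replicate 2 would have to make up a median of 23.3% of it by 278 genes over 4-fold lower in W9706 (quartiles -6.55% and 38.6%), or 13.9% when these genes were chosen from all libraries (95% bootstrap interval 5.72% to 21.4%), while 13 genes over 32-fold higher in W9706, chosen without B73 replicate 2, reached a median of 1.31% of their W9706 level there (0.937% to 4.84%). Mixing into W9706 replicate 1 was not tested, and a difference between plants in how far the drought had progressed stays open as a candidate explanation, untested without watered libraries.

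Fold changes of genes with neighbouring identifier numbers were weakly alike. Identifiers with this prefix run along the chromosomes, so the number serves as a stand-in for position. The correlation was 0.0837 for adjacent tested genes (highest of 100 shuffles 0.0196), 0.0296 for 2 genes apart and 0.00182 for 20 apart (highest shuffle 0.0174). Differences between replicates of a line gave 0.0545 in B73 and 0.0665 in W9706 for adjacent genes. This short range was the one predicted for reads shared between tandem copies or overlapping genes. Joint regulation of neighbours, which was not tested, could also give it. Reads falling in several genes were listed as ambiguous and kept out, so the same read was not counted for both neighbours. No similarity over longer stretches of identifiers was detectable.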
